A study of Mus musculus with 6 samples.

How the data were processed

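RNA of untreated bone marrow-derived macrophages from WT and Lcn10-KO mice was sequenced by the authors in 6 libraries, 3 per genotype. The deposited table holds 24972 rows of gene symbols and 6 columns of values, 1 per library. Per the submitters' processing notes, the tools were bcl2fastq, STAR 2.6.1a, Salmon 0.11.2 and DESeq2 with the genome build mm10, and the notes as used here give neither the role nor the order of these tools. The annotation, the filters and the strand setting of the counting are not given in the sources used here. The deposited values are a signal that the authors scaled from read counts. They are not whole numbers, never fall below 0 and sum to nearly the same total in each library. In low genes the values cluster at multiples of the value of a single read, which was 0.824 to 1.14 depending on the library. Between 84.7% and 90.1% of the low values were whole multiples of it within a tolerance of 0.1 reads, so the rest of the low values could not be turned back into whole reads. A test on read counts was planned for deposited counts and, for scaled values, as an added alternative where whole reads could be recovered. That test was not run. The approximate depth of a library, its total divided by the value of a read, was 18000000 to 24800000 reads.

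Samples were grouped by the genotype in the labels, and columns were matched to samples by the library names there. Genes with a value of at least 10 in at least 3 libraries were tested, which left 12091. Values were turned into log2(value + 1) and fitted with limma 3.58.1 in R 4.3.3, with genotype as the only term, a mean-variance trend and robust estimation, as fixed before the data were examined for scaled values. Log2 fold changes are Lcn10-KO minus WT and are given with their standard error, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Group levels are means ± SD of the deposited values over 3 libraries.

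Gene lists (45) were also fixed before the data were examined, and the 35 with at least 5 tested genes entered camera, with a correlation between genes of 0.01, and fry. The lists of lipocalins, dendritic cells, B cells, T and NK cells, erythroid cells, mast cells, eosinophils, mitochondrially encoded genes, sex-linked genes and histones had too few tested genes. Marker lists were compared by an exact two-sided permutation test of the mean log2 value over genes above 0 in any library. The rule for named genes took *Lcn10*, the 3 Nr4a genes, the 10 largest increases and decreases and the 5 smallest p in each direction among called genes with separated groups, a mean of at least 50 in the higher group and an official symbol that is no predicted model, and up to 4 members of each list by p. Others named were chosen after their values were seen.

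Positions, GC content and transcript length came from the GENCODE annotation of GRCm38, the assembly that mm10 names, and 24538 of 24970 symbols matched by name. Among the rows, 26 carry a date in place of a symbol, as spreadsheets make of some gene names, and these rows were kept in the tests but not named as genes. Genes with near-identical copies, and genes that overlap another on either strand, can share reads, and their values are uncertain.

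The procedure was tested on simulated data for this comparison, with 200 of 12098 genes changed. It recovered 66.0% of genes changed 1.25-fold, 90.0% at 1.5-fold, 92.0% at 2-fold and 96.0% at 4-fold, with 5 false calls among 177, and made 0 calls and passed 0 of 35 lists when no gene was changed. The simulated genes were drawn independently of each other, all with the same biological variability (squared coefficient of variation 0.00137). The simulation therefore cannot show how camera behaves when genes are correlated, or how the recovery changes when variability differs between genes. Alternatives were quantile normalization, rescaling by the median ratio, limma without the trend, other filters on low values, pseudocounts of 0.5 and 10, a replicate block, sex-linked genes left out, each library left out in turn, camera with an estimated correlation, fry and, chosen after the data were seen, removal of each library's trends on GC content and transcript length. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.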

Results

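Gene expression was measured by RNA sequencing in bone marrow-derived macrophages, cells grown out of mouse bone marrow in medium that contains supernatant of L929 cells, a source of macrophage colony-stimulating factor. The macrophages came from wild-type (WT) mice and from mice lacking *Lcn10* (Lcn10-KO), a gene for a small secreted carrier protein of the lipocalin family, and were left untreated. Each genotype had 3 libraries, numbered as replicates in the labels. The labels do not say whether the replicates of a genotype came from separate mice, so p-values measure the spread between these libraries, which may in part be technical. Values are normalized read counts, whose totals lay between 20476700 and 20636300 in the 6 libraries because of the scaling. From the value of a single read, the libraries held about 18000000, 18000000 and 24800000 reads in WT and 19300000, 24400000 and 19800000 in Lcn10-KO. The 10 most abundant genes took 8.33% to 9.08% of each library.

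The targeted gene was looked at first. *Lcn10* (ENSMUSG00000047356.2, chromosome 2, 25682726 to 25686081, plus strand, GRCm38) was listed at 0 in each of the 3 WT and the 3 Lcn10-KO libraries. The gene therefore cannot check the genotype labels in these cells, and no fold change is given. With a value of 0 in WT as well, these data show no *Lcn10* transcript for the Lcn10-KO macrophages to lose. Of the 20 genes of the lipocalin list, 1 passed the filter on low values, *Lcn2*, a siderophore-binding lipocalin. It had a mean of 17.5 ± 2.89 (SD, n = 3) normalized counts in WT and 23.6 ± 7.65 (SD, n = 3) in Lcn10-KO and did not pass the test (log2 fold change 0.38 ± 0.30 (SE), limma adjusted p = 0.467). None of the 15 tested genes of the fixed list of genes next to *Lcn10* on chromosome 2 passed the threshold by limma, either over all genes tested or adjusted over the list alone. At an unadjusted p under 0.05 there were 4 such genes, *Uap1l1*, *Phpt1*, *Dpp7* and *Abca2*, the first with a log2 fold change of 0.11 ± 0.04 (SE, adjusted p = 0.0877). The list was fixed by name and leaves out other genes of chromosome 2. It therefore does not show that the region around *Lcn10* was unchanged. Among the genes left out, *Fcna*, *Bmyc* and *Egfl7* passed the threshold and were over 1.5-fold apart (log2 fold changes −0.63, −0.76 and 1.15). *Xist* lay between 27492 and 30918 normalized counts in the 6 libraries and the 4 Y-linked genes looked at, *Ddx3y*, *Kdm5d*, *Eif2s3y* and *Uty*, did not exceed 3.13, the pattern of female cells.

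The replicates of a genotype resembled each other more closely in Lcn10-KO than in WT. Spearman correlations between libraries over the tested genes were 0.998 within Lcn10-KO, 0.995 to 0.998 within WT and 0.991 to 0.997 between the genotypes. The first principal component held 39.9% of the variance and put the 3 Lcn10-KO libraries at 9.92 to 15.3 and the WT libraries at −26.3, −4.63 and −9.29. On the second component, with 18.5% of the variance, WT replicate 2 lay at −20.4, against 11.5 and −3.65 in WT replicates 1 and 3 and 2.70 to 6.74 in Lcn10-KO. WT replicate 1 thus stood apart on the first axis and WT replicate 2 on the second. No pair of libraries was as close as sampling noise alone would make it, with a variance of at least 1.81 times that of counting.

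**Figure D1:**
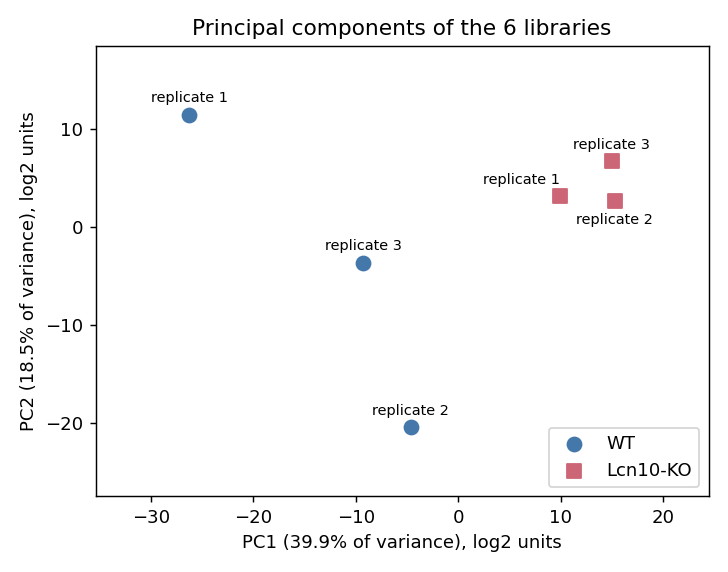
First and second principal components of log2(normalized count + 1) over the tested genes, in log2 units, with 1 point per library (circles WT, squares Lcn10-KO). The Lcn10-KO libraries lie together at 9.92 to 15.3 on the first axis and the WT libraries spread from −26.3 to −4.63, with WT replicate 2 lowest on the second axis, at −20.4.

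The comparison of Lcn10-KO with WT asks which genes differ between the genotypes in resting macrophages. *Lrmda*, a gene linked to melanocyte differentiation, fell the most among the called genes with a mean of at least 50 in the higher genotype and an official symbol, from 99.5 ± 12.9 to 11.3 ± 0.613 normalized counts (mean ± SD, n = 3 per genotype). Its log2 fold change was −3.02 ± 0.21 (SE). *Rab4a*, a small GTPase of endosome recycling, rose from 59.8 ± 9.39 to 236 ± 11.7, and *Wdfy1*, an adaptor of Toll-like receptor signalling, from 408 ± 18.8 to 975 ± 53.9. *Nnt*, the mitochondrial nicotinamide nucleotide transhydrogenase, rose from 700.2 ± 40.3 to 1420 ± 40.5. *Mid1*, a microtubule-associated ubiquitin ligase, and *Notch4*, a Notch receptor, fell by 1.40 and 1.39 on the log2 scale. In all, 1190 of 12091 tested genes differed (9.84%), of which 568 were higher and 622 lower in Lcn10-KO. Most changes were small, with a median absolute log2 fold change of 0.27. Over 1.5-fold apart were 135 genes, 74 higher and 61 lower, and over 2-fold apart were 24 higher and 22 lower. The test was limma with a mean-variance trend and Benjamini-Hochberg adjusted p under 0.05, on log2(value + 1), a scale that understates the change of low genes. The 3 values of one genotype all lay above the 3 of the other in 1189 of the 1190 genes and in 32.4% of the tested genes, against 10% by chance. The count fell to 14 genes (13 over 1.5-fold apart) in limma without the trend, and to 567, 206 and 173 genes without Lcn10-KO replicate 1, 2 or 3. The genes over 1.5-fold apart numbered 50 without Lcn10-KO replicate 2, 38 without Lcn10-KO replicate 3 and 223 without WT replicate 2.

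Among the 10 genes with the largest increases, besides *Rab4a* and *Wdfy1*, several code for receptors or surface proteins. *Ednrb*, the endothelin B receptor, rose from 114 ± 33.9 to 333 ± 68.2 normalized counts (log2 fold change 1.56 ± 0.26 (SE), adjusted p = 0.0173). *Cd4*, the T cell coreceptor that some macrophages also carry, rose from 47.6 ± 15.8 to 131 ± 8.51 (adjusted p = 0.00496). Its neighbour on chromosome 6, the orphan receptor gene *Gpr162*, had a log2 fold change of 1.43 ± 0.15 (adjusted p = 0.000222). *Stab2*, a scavenger receptor for hyaluronan, rose by 1.30 ± 0.26, *P2ry14*, a receptor for UDP-glucose, by 1.20 ± 0.23, and *Cd59a*, an inhibitor of the complement membrane attack complex, by 1.11 ± 0.09 on the log2 scale. *Camk2b*, a calcium/calmodulin-dependent kinase, and *Efcab7*, an EF-hand protein, had log2 fold changes of 1.52 ± 0.20 and 1.44 ± 0.20. *Stab2*, which endothelial cells also express, lay at 42.6, 81.3 and 71.9 in Lcn10-KO replicates 1 to 3, and the endothelial marker *Pecam1* at 49.5, 161 and 89.3 in the same libraries. *Fabp5*, a fatty acid-binding protein, was among the 5 increases with the smallest p, at 9514 ± 498 in WT and 13463 ± 514 in Lcn10-KO (adjusted p = 0.000127).

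Next to *Lrmda* by the same rule, *Id3*, an inhibitor of basic helix-loop-helix factors, fell from 950.4 ± 287 to 353 ± 67.2 normalized counts (log2 fold change −1.40 ± 0.26, adjusted p = 0.0393). *Dmpk*, a serine/threonine kinase, had a log2 fold change of −1.40 ± 0.21 (adjusted p = 0.0222), and *Mid1* and *Notch4* had adjusted p of 0.00128 and 0.000222. *Tmem26*, *Tiam2* (a Rac exchange factor), *Fgf11*, *Cspg4* (a chondroitin sulfate proteoglycan) and *Ch25h* (cholesterol 25-hydroxylase) had log2 fold changes of −1.32 ± 0.16, −1.27 ± 0.34, −1.17 ± 0.23, −1.17 ± 0.27 and −1.09 ± 0.27. *Wwc2*, a regulator of Hippo signalling, and *Gdf3*, a growth factor of the transforming growth factor beta family, had small errors and fell by 1.06 ± 0.08 and 0.88 ± 0.07 on the log2 scale. *Tmem254b* (−0.89 ± 0.07) and *Entpd4b* (−0.66 ± 0.06) have near-identical copies in the genome, so their own values are uncertain. The sums over the listed copies moved alike, with Lcn10-KO at 0.547 times WT for the Tmem254 copies and at 0.626 times WT for the Entpd4 copies. *Mid1* overlaps *G530011O06Rik* on the opposite strand, which had a log2 fold change of −0.72, and without known strand use reads from the pair cannot be told apart. Of the 26 genes named for size or p, 17 stayed past the threshold when any 1 library was left out. Past it in limma without the trend as well were 9 of these, *Lrmda*, *Rab4a*, *Wdfy1*, *Nnt*, *Cd59a*, *Wwc2*, *Gdf3*, *Tmem254b* and *Entpd4b*. Lost in at least 1 leave-out were *Ednrb*, *Stab2*, *P2ry14*, *Id3*, *Dmpk*, *Tiam2*, *Fgf11*, *Cspg4* and *Ch25h*, with adjusted p of up to 0.130, each of them without Lcn10-KO replicate 3. *Id3* also lost its call with no filter on low values (adjusted p = 0.0628).

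**Figure D2:**
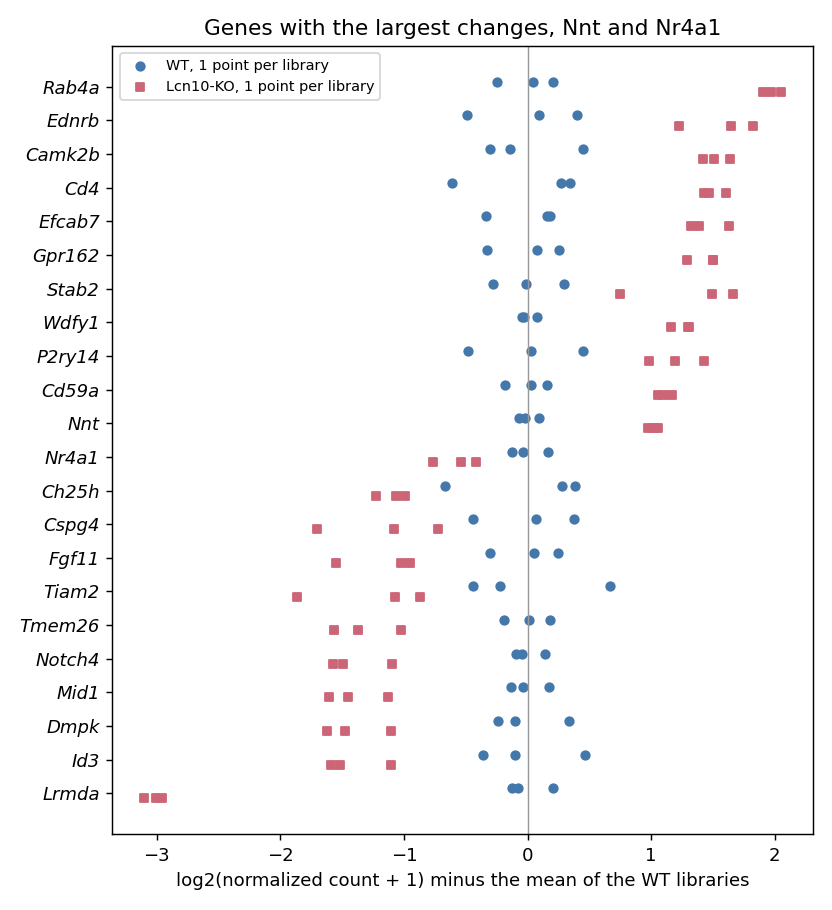
Values of the genes with the largest increases and decreases, of *Nnt* and of *Nr4a1*, as log2(normalized count + 1) minus the mean of the WT libraries, with 1 point per library (circles WT, squares Lcn10-KO). *Lrmda* lies farthest to the left, at a log2 fold change of −3.02, and *Rab4a* farthest to the right, at 1.97.

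Gene lists fixed before the data were examined were tested with camera, which asks whether the genes of a list move against all other genes, at a preset correlation of 0.01 between genes. Of 35 lists large enough to test, 10 passed an adjusted p under 0.05, 6 toward higher and 4 toward lower values in Lcn10-KO. With an estimated correlation in camera 0 of the 35 passed, the smallest adjusted p being 0.647 (1 list at an unadjusted p under 0.05). In contrast fry, which asks whether a list moves one way on balance, passed 5 lists and its mixed form, which asks whether genes change in either direction, 22. The 5 were lysosome and autophagy, ER stress, cholesterol efflux, fatty acid oxidation and the genes next to *Lcn10*, each at an adjusted p of 0.0273. Lists also passed camera when the 6 libraries were split in other ways that mix the genotypes, with up to 18 lists in 1 such split. Of the 106 named genes past the limma threshold, 45 stayed past it without Lcn10-KO replicate 2, 43 without Lcn10-KO replicate 3 and 9 in limma without the trend. Quantile normalization ended the calls of *Adgre1*, *B2m*, *Ccl9*, *Ctsb* and *Nod1* (limma adjusted p of 0.0559 to 0.309), removal of trends on GC content and transcript length those of *Adgre1*, *Bcl2a1b*, *Nod1* and *Rps14* (0.0508 to 0.102), and the absence of a filter on low values that of *Atp6v0d2* (0.0557).

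Of 29 members of the lysosome and autophagy list, 12 were higher, 0 lower and 17 not past the threshold, against 16 higher adjusted over the list alone. The median log2 fold change was 0.13 (camera adjusted p = 1.56e-06, and adjusted p = 0.647 with an estimated correlation). *Psap*, the precursor of the saposins, rose from 119055 ± 1538 to 150537 ± 4899 normalized counts (log2 fold change 0.34 ± 0.04), and *Ctsb*, the protease cathepsin B, by 0.21 ± 0.04. Under quantile normalization the log2 fold change of *Psap* was 0.19 and that of *Ctsb* 0.063, which did not pass (adjusted p = 0.309). Among the WT libraries the mean of the list was lowest in WT replicate 1, at −0.11 log2 units around the average of all 6 against −0.04 and −0.05. *Gabarapl1*, which acts in autophagosome formation, rose by 0.32 ± 0.05 and *Atp6v1a*, a subunit of the proton pump that acidifies lysosomes, by 0.27 ± 0.05. The macrophage identity list had 4 of 18 genes higher and 1 lower, against 5 and 2 adjusted over the list alone. The list had a median log2 fold change of 0.09 (camera adjusted p = 0.0354, and adjusted p = 0.647 with an estimated correlation). *Lgals3*, *Cd63* and *Adgre1*, which codes for the surface marker F4/80, had log2 fold changes of 0.23 ± 0.04, 0.24 ± 0.04 and 0.26 ± 0.06, whereas *Csf1r*, the receptor of macrophage colony-stimulating factor, fell by 0.23 ± 0.05. This list lost its call without WT replicate 1 (camera adjusted p = 0.0585) and without WT replicate 3, Lcn10-KO replicate 1 or Lcn10-KO replicate 2 (0.0748, 0.0827 and 0.0826), under quantile normalization (0.0685) and after removal of trends on GC content and transcript length (0.119).

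In the list of cholesterol efflux genes and targets of the liver X receptor (LXR), 6 of 17 genes were higher, 1 lower and 10 not past the threshold, and the same numbers passed adjusted over the list alone. Across its genes the median log2 fold change was 0.09 (camera adjusted p = 0.00204, and adjusted p = 0.647 with an estimated correlation). *Abcg1*, a cholesterol exporter, rose from 968 ± 123 to 1463 ± 95.3 normalized counts (log2 fold change 0.60 ± 0.09), *Pltp*, the phospholipid transfer protein, by 0.42 ± 0.06 and *Nr1h3*, which codes for LXR alpha, by 0.40 ± 0.08, while *Smpdl3a* fell by 0.25 ± 0.05. Here too WT replicate 1 lay lowest, at −0.15 against −0.06 and −0.10 in the other WT libraries. The cholesterol synthesis list passed with 1 of 23 genes called, *Fdft1*, squalene synthase (0.33 ± 0.08, adjusted p = 0.0210). Adjusted over the list alone it was also 1 gene, and the median was 0.16 (camera adjusted p = 0.00179, and adjusted p = 0.780 with an estimated correlation). In this list WT replicate 1 lay far below the other libraries, at a mean of −0.26 log2 units around the average of all 6 against 0.01 and 0.00 in the other WT libraries and 0.06 to 0.12 in Lcn10-KO. Without it the median was 0.077 (camera adjusted p = 0.0360). *Fabp5* and *Fabp4* were the 2 genes past the threshold, both higher, of the 20 of fatty acid oxidation and lipid droplets (4 higher and 1 lower adjusted over the list alone), a list that did not pass camera (adjusted p = 0.141). *Fabp4* rose by 0.63 ± 0.07 on the log2 scale.

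In the cell cycle list 13 of 40 genes were lower, 2 higher and 25 not past the threshold, against 17 lower and 2 higher adjusted over the list alone. The median log2 fold change was −0.04 (camera adjusted p = 0.0400, and adjusted p = 0.816 with an estimated correlation). *Mcm4* and *Mcm3*, subunits of the replicative helicase, fell by 0.34 ± 0.05 and 0.31 ± 0.05 on the log2 scale, *Ccne2*, cyclin E2, by 0.47 ± 0.08 and *Cdc6*, a replication licensing factor, by 0.35 ± 0.07. Singled out after the values were seen, *Cenpa* and *Ccnb2*, which act in mitosis, were the 2 genes that rose. The median ranged from −0.064 without WT replicate 2 to −0.0098 without WT replicate 3 (−0.062 without Lcn10-KO replicate 3, −0.022 and −0.015 without Lcn10-KO replicate 1 or 2). The list means of single libraries overlapped, with WT replicate 2 at −0.03 below Lcn10-KO replicate 3 at −0.01, and the call was lost without WT replicate 3, Lcn10-KO replicate 1 or Lcn10-KO replicate 2 (camera adjusted p = 0.407, 0.147 and 0.0826), under quantile normalization (0.0819), with a stricter filter on low values (0.0534) and after removal of trends on GC content and transcript length (0.0609).

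The list of endoplasmic reticulum stress and amino acid response genes had 7 of 23 genes lower and 0 higher (10 lower and 1 higher adjusted over the list alone) and a median log2 fold change of −0.10 (camera adjusted p = 0.00179, and adjusted p = 0.647 with an estimated correlation). *Asns*, asparagine synthetase, fell by 0.36 ± 0.06, and the chaperones of the endoplasmic reticulum *Calr*, *Hspa5* and *Pdia4* by 0.22 ± 0.04, 0.18 ± 0.04 and 0.17 ± 0.04. The list mean lay at 0.12 in WT replicate 1, against 0.02 and 0.04 in the other WT libraries and −0.07 to −0.05 in Lcn10-KO. Glycolysis had 4 of 20 genes lower and 1 higher, against 12 and 2 adjusted over the list alone. The list had a median log2 fold change of −0.22 (camera adjusted p = 0.00487, and adjusted p = 0.709 with an estimated correlation). *Pkm*, pyruvate kinase, fell by 0.28 ± 0.06, *Pgk1*, phosphoglycerate kinase, by 0.24 ± 0.06 and *Hk1*, a hexokinase, by 0.23 ± 0.06, while *Hk3*, a hexokinase of myeloid cells, rose by 0.17 ± 0.04. The mean of this list in WT replicate 1, at 0.20 log2 units above the average of all 6 libraries, stood apart from the other WT libraries at 0.05 and −0.01 and from Lcn10-KO at −0.12 to −0.04. Without it the median was −0.13 (camera adjusted p = 0.00467).

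Of 22 genes in the list of Nr4a and immediate early genes, 4 were lower and 1 higher, against 6 and 1 adjusted over the list alone. Across its genes the median log2 fold change was −0.08 (camera adjusted p = 0.00979, and adjusted p = 0.647 with an estimated correlation). *Nr4a1*, an orphan nuclear receptor that is induced in macrophages by many stimuli, fell from 199.8 ± 21.2 to 134 ± 16.5 normalized counts (log2 fold change −0.57 ± 0.12, adjusted p = 0.0155), a call lost without Lcn10-KO replicate 2 or 3, with an adjusted p of up to 0.0811, and in limma without the trend (0.108). Its relative *Nr4a2* had a log2 fold change of −0.41 ± 0.23 (adjusted p = 0.273) at 30.6 ± 0.907 normalized counts in WT, and *Nr4a3* one of 0.02 ± 0.68 (adjusted p = 0.991) at values between 1.65 and 16.0, a sign that turned under quantile normalization, with a pseudocount of 10 and without WT replicate 3, Lcn10-KO replicate 1 or Lcn10-KO replicate 3. *Fosb*, *Fosl2* and *Dusp1* had log2 fold changes of −1.18 ± 0.26, −0.35 ± 0.06 and −0.32 ± 0.06. The list median was −0.14 under quantile normalization, −0.17 without WT replicate 3 and −0.19 without Lcn10-KO replicate 1. Its call was lost with a stricter filter on low values, a minimum of 50 (camera adjusted p = 0.0779).

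The NF-kB list passed with 2 of 19 genes higher and 0 lower, against 9 higher and 1 lower adjusted over the list alone. The median log2 fold change was 0.15 (camera adjusted p = 0.0284, and adjusted p = 0.709 with an estimated correlation). These were *Tnfaip2* (0.38 ± 0.05) and *Bcl2a1b* (0.21 ± 0.06), an apoptosis inhibitor with near-identical copies whose value is uncertain. The inflammasome list had 3 of 16 genes higher and 1 lower, against 7 and 1 adjusted over the list alone. The list had a median log2 fold change of 0.10 (camera adjusted p = 0.0412, and adjusted p = 0.709 with an estimated correlation). *Nlrp3*, the sensor that gives the NLRP3 inflammasome its name, was the gene that fell (by 0.31 ± 0.05), and *Ninj1*, *Casp4* and *P2rx7* had log2 fold changes of 0.25 ± 0.04, 0.41 ± 0.11 and 0.23 ± 0.07. The NF-kB call was lost without WT replicate 3 or Lcn10-KO replicate 1 (camera adjusted p = 0.0748 and 0.121), and the inflammasome call without WT replicate 1, WT replicate 3, Lcn10-KO replicate 1 or Lcn10-KO replicate 2 (0.172, 0.0955, 0.0687 and 0.0856).

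**Figure D3:**
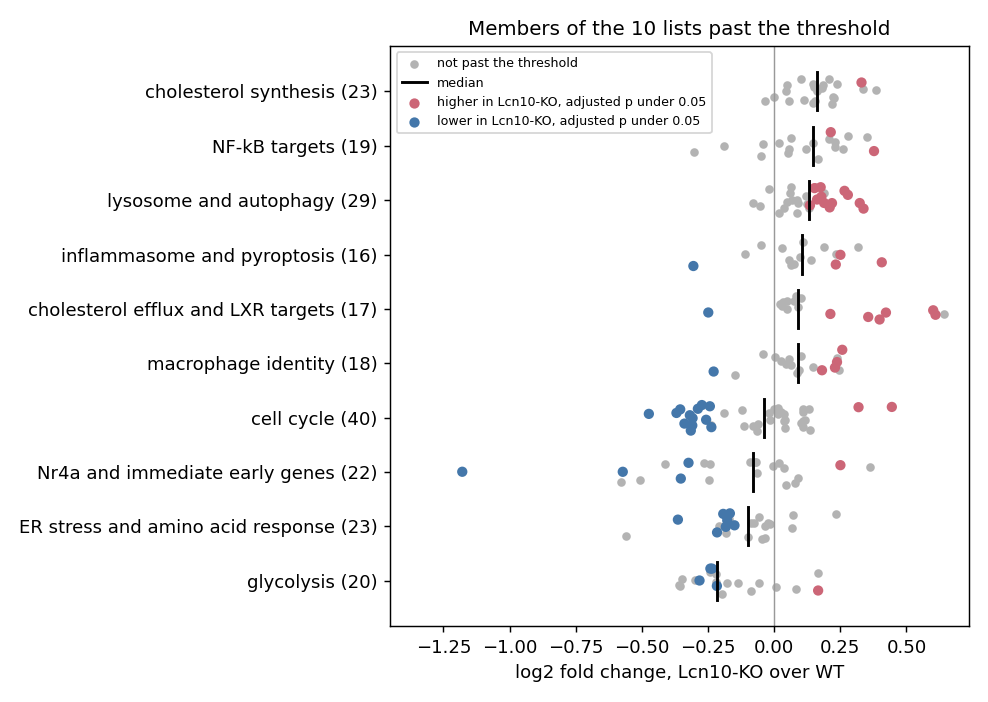
Log2 fold changes (Lcn10-KO over WT) of the members of the 10 lists past the camera threshold, with 1 point per gene, the number of genes in brackets and the list median as a bar. Coloured points passed an adjusted p under 0.05 in limma, red for higher and blue for lower, as for 12 higher genes of the lysosome list.

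**Figure D4:**
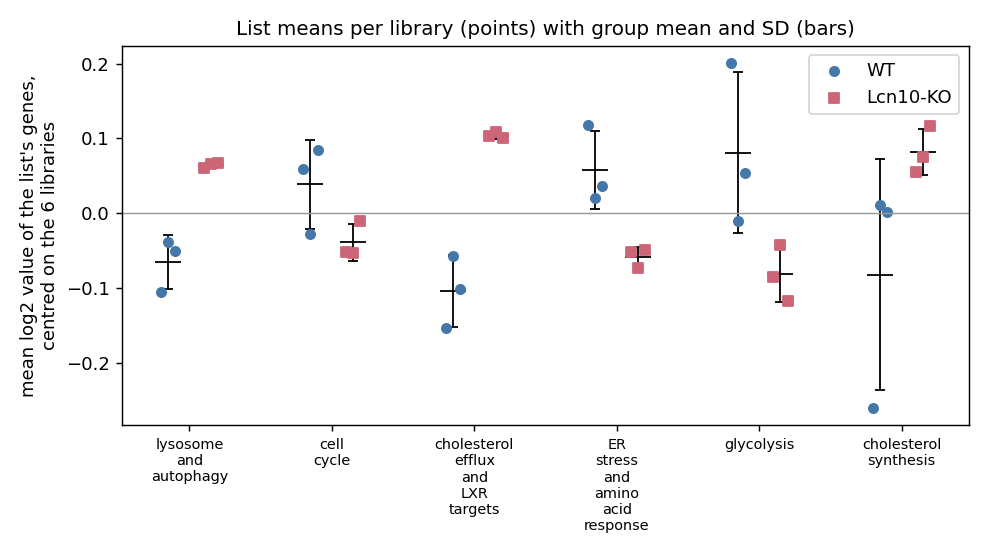
Mean log2(normalized count + 1) of the genes of 6 lists in each library, centred on the 6 libraries (circles WT, squares Lcn10-KO), with the group mean as a dash and the SD as a bar. WT replicate 1 lies at −0.26 in the cholesterol synthesis list and at 0.20 in the glycolysis list.

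The lists of inflammatory output did not pass. None of the 13 tested pro-inflammatory mediators passed limma (0 adjusted over the list alone, 3 at an unadjusted p under 0.05, camera adjusted p = 0.773). The list median was 0.13 and camera pointed up. *Tnf* had a log2 fold change of −0.23 ± 0.07 (adjusted p = 0.0734, but 0.0402 after removal of trends on GC content and transcript length). *Ptgs2*, an enzyme of prostaglandin synthesis, had one of −0.86 ± 0.33 (adjusted p = 0.147). *Il1a*, which had low values, went the other way, at 1.22 ± 0.46 (adjusted p = 0.116). Likewise 0 of 31 interferon-stimulated genes passed limma (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, camera adjusted p = 0.773), with *Ifi27l2a* at 0.83 ± 0.22 (adjusted p = 0.0908). In the alternative activation list 2 of 15 genes were lower, *Klf4*, a transcription factor, by 0.41 ± 0.08 and *Arg1*, arginase, from 28.2 ± 2.88 to 9.45 ± 5.37 normalized counts (log2 fold change −1.62, or −1.01 with a pseudocount of 10, adjusted p = 0.0244 and 0.0179), and 0 were higher. Adjusted over the list alone, 2 were lower and 2 higher, and the list did not pass camera (adjusted p = 0.585). *Mrc1*, the mannose receptor, had a log2 fold change of 0.59 ± 0.16 (adjusted p = 0.0838, but 0.0498 without WT replicate 1). Of 13 chemokines, *Cxcl14* fell from 1427 ± 166 to 823 ± 127 and *Ccl9* rose by 0.22 ± 0.06 on the log2 scale (0.15 without WT replicate 1). Adjusted over the list alone, 1 was lower and 1 higher as well (camera adjusted p = 0.988). Pattern recognition receptors had 3 of 24 genes higher, *Tlr6*, *Ticam2* and *Nod1* (0.32 ± 0.07, 0.41 ± 0.09 and 0.45 ± 0.13), and 1 lower, *Cd14*, a coreceptor for lipopolysaccharide (−0.17 ± 0.05). Adjusted over the list alone, 8 were higher and 1 lower (camera adjusted p = 0.229).

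Surface receptors and matrix genes changed in both directions. Among 24 scavenging and efferocytosis receptors, 5 were higher and 4 lower (6 and 4 adjusted over the list alone, camera adjusted p = 0.332). *Mertk*, a receptor for apoptotic cells, and its ligand *Gas6* rose by 0.44 ± 0.06 and 0.26 ± 0.05 on the log2 scale, whereas *Itgav*, integrin alpha V, fell from 7378 ± 418 to 4910 ± 413 normalized counts and *Lrp1*, a scavenger receptor, by 0.25 ± 0.06. Of 23 adhesion and migration genes, 5 were lower and 3 higher (6 and 5 adjusted over the list alone, camera adjusted p = 0.773). Camera and the list median of 0.10 pointed up where fry pointed down. *Itgal*, integrin alpha L, fell by 0.96 ± 0.12, *Cx3cr1*, the fractalkine receptor, from 1846 ± 87.8 to 1168 ± 110 and *Itga6* by 0.42 ± 0.04, while *Rhob* had a log2 fold change of 0.26 ± 0.05. Matrix remodelling had 5 of 24 genes lower and 3 higher (5 and 4 adjusted over the list alone, camera adjusted p = 0.526). Among them were *Tgfbi* (−0.54 ± 0.05), *Spp1*, osteopontin (−0.48 ± 0.07), *Timp2* (0.42 ± 0.05) and *Mmp27* (0.66 ± 0.11). In the angiogenic and growth factor list 3 of 18 genes were lower, *Nrp1*, *Pdgfb* and *Sema3c* (−0.18 ± 0.04, −0.27 ± 0.07 and −1.21 ± 0.33), and 0 higher. The numbers adjusted over the list alone were 6 lower and 3 higher (camera adjusted p = 0.726).

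Antigen presentation genes of MHC class I had 4 of 16 members higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 0.133). *H2-D1*, *H2-Q4*, *H2-K1* and *B2m* had log2 fold changes of 0.26 ± 0.04, 0.37 ± 0.07, 0.25 ± 0.05 and 0.20 ± 0.06. The H2 genes share sequence with their relatives, so their values are uncertain. None of the 9 tested MHC class II genes passed limma over all genes (2 higher adjusted over the list alone, 2 at an unadjusted p under 0.05, camera adjusted p = 0.303). Of 20 p53 and apoptosis genes, 4 were higher and 1 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.303). Log2 fold changes were for *Gadd45a*, a growth arrest gene, 0.52 ± 0.09, for *Mcl1* 0.28 ± 0.06 and for *Cdkn1a*, the inhibitor p21, −0.31 ± 0.07. Of 25 NRF2 targets, 3 were higher and 2 lower (3 and 3 adjusted over the list alone, camera adjusted p = 0.885), and camera pointed down where fry pointed up. *Mgst1* had a log2 fold change of 0.51 ± 0.08 and *Taldo1* one of −0.25 ± 0.04. Hypoxia targets had 3 of 17 genes lower, *P4ha1*, *Hif1a* and *Ero1l* (−0.35 ± 0.07, −0.16 ± 0.04 and −0.21 ± 0.06), and 1 higher, *Bnip3l* (0.19 ± 0.05). The numbers adjusted over the list alone were 3 lower and 2 higher (camera adjusted p = 0.773). In the retinoid list *Dhrs3*, a retinal reductase, was the 1 of 13 genes that passed (0.27 ± 0.05), against 2 higher adjusted over the list alone (camera adjusted p = 0.972). Here camera pointed down where fry and the median pointed up. Oxidative phosphorylation had 1 of 41 genes past the threshold, *Cycs*, cytochrome c (−0.26 ± 0.06), and 0 adjusted over the list alone (camera adjusted p = 0.320). The 37 ribosomal protein genes also had 1, *Rps14* (0.16 ± 0.04), and 0 adjusted over the list alone (camera adjusted p = 0.177). Mitochondrially encoded genes had no rows and could not be used as a sign of RNA quality.

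Marker sums of 7 other cell types (neutrophils, B cells, T and NK cells, erythroid, stromal, mast and eosinophil cells) made up at most 0.0577% of a WT library. The Ly6C monocyte list made up 0.0804% in WT and 0.0730% in Lcn10-KO, and the osteoclast list 0.0601% and 0.0708%. Of 5 tested genes of Ly6C monocytes 1 was lower, *F13a1*, a coagulation factor (−0.61 ± 0.13), and of 9 genes of neutrophils and granules 1 was higher, *Csf3r*, a colony-stimulating factor receptor (0.50 ± 0.12), with camera adjusted p of 0.177 and 0.260. Of 10 osteoclast genes, *Atp6v0d2*, a proton pump subunit, was higher, at 3549 ± 620 normalized counts in WT and 6182 ± 493 in Lcn10-KO, and *Tnfrsf11a*, the receptor RANK, lower (−0.25 ± 0.06). Among 7 genes of megakaryocytes and endothelium *Egfl7* was higher (1.15 ± 0.27), and the list median was 0.66. *Pecam1* and *Emcn* had log2 fold changes of 0.83 ± 0.44 and 0.92 ± 0.54 and did not pass (adjusted p = 0.294 and 0.349), with *Emcn* at 24.5, 121 and 62.4 in Lcn10-KO replicates 1 to 3 against 30.7, 31.8 and 27.2 in WT. Both passed without Lcn10-KO replicate 1 (adjusted p = 0.0462 and 0.0162). The list made up 0.00265% of the library in WT and 0.00329% in Lcn10-KO. Camera gave an adjusted p of 0.331 for both the osteoclast list and this one. Limma called 0 of 6 progenitor genes (1 at an unadjusted p under 0.05) and 0 of 14 stromal genes (0 at an unadjusted p under 0.05), at a camera adjusted p of 0.773 each. Adjusted over the list alone, the higher genes of these 6 lists numbered 0, 1, 3, 1, 0 and 0 and the lower ones 1, 0, 1, 0, 0 and 0. The mean of the genes of a marker list was also compared between genotypes by an exact two-sided permutation test over 16 lists, in which 3 against 3 libraries cannot give a p below 0.1. In this permutation test that smallest p was met by the macrophage identity, B cell, erythroid and eosinophil lists, with log2 differences of 0.09, 0.44, 0.54 and 0.54, and by the histone and non-polyadenylated list at −0.36, whose share of the library went the other way, from 0.00339% ± 0.000115 (SD, n = 3) in WT to 0.00420% ± 9.69e-05 in Lcn10-KO. The adjusted p of each was 0.320. The dendritic cell, T and NK cell and sex-linked lists, at 0.09, 0.14 and 0.03, and the mast cell list, at −0.0035, did not meet it. Genes of the erythroid and B cell lists lay near the floor, at a mean log2 value of 0.98 and 1.38 in WT. By medians in place of means the permutation p was 0.6 for the erythroid list. It was 0.2 for the macrophage identity, B cell and eosinophil lists and 0.1 for the histone list.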

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

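Removal of GC content and transcript length trends was the alternative chosen after the data were seen; it gave 1288 genes, 40.7% of them higher against 47.7%. Under quantile normalization, rescaling, other filters, pseudocounts and without sex-linked genes the genes that differed numbered 1091 to 1279 and those over 1.5-fold apart 108 to 154. Limma without the trend gave 14 and 13, and the cause was not tested. With a library left out they ranged from 173 to 1652 and from 38 to 223, where fewer samples entered, and lists past camera from 6 to 12. An estimated correlation left 0 lists and fry 5, and the cause was not tested. A replicate block gave 1607 and 181 genes and 7 lists. With it the macrophage identity, cell cycle and inflammasome lists lost their calls (camera adjusted p = 0.0552, 0.0766 and 0.0552), and so did *Tiam2* (limma adjusted p = 0.0683). In turn *Mrc1*, *Ptgs2* and *Pecam1* passed limma with the block (adjusted p = 8.22e-06, 0.00783 and 0.0138). Same-numbered libraries correlated in their deviations by 0.04, 0.07 and 0.01, and differently numbered ones by −0.06 to 0.03. WT replicates 1 and 2 correlated best with the library of the same number, but WT replicate 3 with Lcn10-KO replicate 1 (0.03). The labels do not say whether the numbers pair the libraries, and values this small do not decide it. Of the genes past the threshold in the main test, 1 changed sign, under quantile normalization. *Nr4a3* turned to −0.19 under quantile normalization and −0.067 with a pseudocount of 10, and ranged from −0.78 to 0.57 with a library left out. By medians in place of means, marker differences turned for Ly6C monocytes (−0.067), T and NK cells (−0.066), stroma (−9.44e-05), mast cells (0.20) and sex-linked genes (−0.47), and the cause was not tested. As a share of the library total *Lcn10* stayed at 0. DESeq2, edgeR factors and voom need counts and were not run. Depth limits what low genes can show: a read is worth 0.824 to 1.14, and the median SE of 0.07 leaves small changes undetected.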

Other observations

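The families of genes in this paragraph and the next, the single genes named in them, the removal of GC content and transcript length trends, the separate reading of the lysosome and cell cycle lists without WT replicate 1 and the tests of strain background were chosen after the results were seen. Members of the translation and growth machinery were lower in Lcn10-KO in several families, most of which no fixed list covers. The fixed list of 37 ribosomal protein genes did not go this way, with 1 higher, 0 lower and a median log2 fold change of 0.03 (camera adjusted p = 0.177). Of 39 ribosome biogenesis factors, 14 were lower and 0 higher (median log2 fold change −0.19), with *Rrp12* at −0.48 and *Nop58* at −0.37. Of 20 cytosolic aminoacyl-tRNA synthetases, 8 were lower and 0 higher, and all 20 had a negative fold change. Lower also were 9 of 23 importins and exportins, 4 of 19 nucleoporins, 3 of 5 subunits of RNA polymerase I, 3 of 8 subunits of the CCT chaperonin, 8 of 19 HSP90 and HSP70 chaperones and cochaperones and 6 of 6 MCM helicase subunits, with 0 higher in each. On the other side, 7 of 18 V-ATPase subunits were higher and 0 lower, as were 6 of 12 genes of the folliculin and Rag GTPase complex, which signals amino acid supply at the lysosome, among them *Rragd* (0.44) and *Flcn* (0.41). Over the 14 families looked at, camera gave adjusted p of up to 0.00864, but of at least 0.203 with an estimated correlation. By a one-sided Fisher's exact test of their called genes the nucleoporins did not pass (adjusted p = 0.1098), and the other families had adjusted p of up to 0.0393. Because the families were picked from the called genes, this is no independent evidence.

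Further families on the cell surface and in the cytoskeleton moved in one direction among called genes. Of 11 formins, which build actin filaments, 6 were lower and 0 higher, and of 19 integrins 5 were lower and 0 higher. Of 8 Fc gamma and paired immunoglobulin-like receptors, 5 were higher and 0 lower, with *Fcgr4* at 0.61, and 3 of 6 Ms4a genes were higher and 0 lower, with *Ms4a6c* at 0.54. Both of the last families hold close relatives that share reads, so single members are uncertain. *Gm45935*, a predicted model that has no match in the annotation, was listed at 0 in the 3 Lcn10-KO libraries and at 18.3, 30.6 and 51.1 in the WT libraries.

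The count of 1190 genes was met in 1 of 10 splits of the 6 libraries, the real one, and the highest other split gave 1 gene. For genes over 1.5-fold apart the real split gave 135 and the highest other 1, again with 1 of 10 splits as large. With 10 splits no share under 0.05 can be had. The 10 lists past camera were met or exceeded in 3 of 10 splits, the highest other being 18 lists when WT replicate 1, WT replicate 3 and Lcn10-KO replicate 3 stood against the rest.

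The pattern of lysosomal genes higher and cell cycle genes lower, which passed camera at the preset correlation and not with an estimated one (adjusted p = 0.647 and 0.816), was weighed against 3 technical explanations. WT replicate 1 as its source is argued against for the lysosome list, whose library means did not overlap between the genotypes without it (median 0.10 against 0.13, camera adjusted p = 7.81e-06). This source stays open for the cell cycle list, which without WT replicate 1 kept its call (camera adjusted p = 0.0205, median −0.055 against −0.039), but whose library means overlapped with and without it. The condition that library means must not overlap was added after the results were seen, and with so few libraries it is weak evidence. A loss of neutrophils, lymphocytes, erythroid, stromal, mast or eosinophil cells is argued against by their marker genes, which made up at most 0.0577% of a WT library, while monocytes, osteoclasts, dendritic cells, progenitors, megakaryocytes and endothelial cells were not part of this test. Trends on GC content and transcript length as the whole cause are argued against for the lysosome list (median 0.12 and adjusted p = 2.31e-06 after their removal) and stay open for the cell cycle list, whose adjusted p rose to 0.0609 while its median log2 fold change stayed at −0.04. An effect of the genotype stays among the open explanations, as untested, since no value here parts it from differences in the timing or density of the cultures.

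The largest single-gene changes were weighed against differences in the genomes of the mice. DNA of another strain carried along around *Lcn10* is argued against as the whole cause, since only 2.99% of the genes over 1.5-fold apart lay within 20 Mb of it (4 of 134), against 2.12% of the tested genes (Fisher's exact test, two-sided p = 0.373). An effect limited to the genes nearest to *Lcn10* stays open, since so wide a window says little about it. The fixed list of genes next to *Lcn10* passed fry (adjusted p = 0.0273, and 0.000267 in its mixed form) but not camera (adjusted p = 0.260). Outside that list, *Fcna* and *Bmyc*, which lie 80.9 kb apart on chromosome 2, were lower and *Egfl7*, 879 kb from *Bmyc*, was higher. How far these genes lie from *Lcn10* is not given here, so a local effect on them stays open. A different substrain background of the mice stays open. *Nnt*, which is deleted in part in the substrain C57BL/6J, differed between the genotypes by 1.02 on the log2 scale. Of the genes over 1.5-fold apart, 17 pairs lay within 1 Mb of each other, against a median of 14 and a 95th percentile of 20 in 10000 random draws of tested genes. Scattered single variants would not raise this number of pairs, so it does not decide on a substrain background. A strain difference could thus be a source of changes such as that of *Nnt*, and it cannot be told apart from an effect of *Lcn10* because the background of the mice is not given in the sources used here.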
